A study of Aplysia californica with 8 samples.

How the data were processed

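RNA of pleural ganglia of Aplysia californica was measured on 8 two-colour Agilent arrays, 24 h after long-term sensitization training. Per the labels' protocols, shocks were given to 1 side of the body in 4 rounds 30 min apart, each round of 10 pulses of 500 ms (60 Hz biphasic) at 90 mA. Ganglia of 2 animals trained on opposite sides were combined per array, 300 ng of total RNA of each side was amplified and labelled, and the trained side was hybridised against the untrained side of the same animals. Each array was therefore 1 replicate with its own within-animal control, and n was 8 arrays.

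The deposited scanner files hold spot intensity values, with green for Cy3 and red for Cy5, made with Feature Extraction 11.5.1.1 per the file headers. The columns used as main input were the mean pixel intensity of each spot and the median intensity of its local background, neither of them normalized per the file headers. The scanner software's processed signals, which are background-subtracted and dye-normalized per the file headers, served as an alternative; its log10 ratio of red over green, per the file headers, was used to check channel direction and correlated across spots with the ratios computed here at 0.687 to 0.765. The authors' deposited value table gives a log2 ratio of Cy5 over Cy3 per spot. Its scale and direction were found by setting each column against the normalized log2 ratios of Cy5 over Cy3 computed here from the scanner files. The r across spots was 0.945 to 0.973, the slope was 1.08 to 1.11, and the column medians were 0.0016 to 0.0073. The submitters' processing notes name limma, and the authors' other steps for that table are not given in the sources used here.

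The channel labels put trained tissue in Cy5 on replicates 1 to 4 and in Cy3 on replicates 5 to 8, and those labels set the direction of every ratio. A sentence of the label protocol reads as if trained tissue was always in Cy5, and that reading was run as an alternative. All 8 arrays were on 1 slide, and the 2 dye orientations lay in different tiers of it, so tier and orientation coincided.

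Intensities were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with control spots at weight 0. Between 0 and 5 non-control spots per array were left out because the scanner software marked them as non-uniform or as outliers, and no non-control spot was saturated. Spots with the same 60-base sequence were averaged, which left 50354 probes from 61657 non-control spots. A probe was tested if it was well above background in either channel on at least 4 arrays, which 37427 probes were. The limma fit had a trained-against-untrained coefficient and a probe-specific dye coefficient, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 ratios include the offset of 50 and so understate changes of dim probes.

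The array names its probes by 26060 sequence entries, most of them identifiers of cloned cDNA sequences. Some named entries are given below by the name of their probe instead of their longer identifier. An entry was represented by its tested probe of highest mean brightness, and 37 probes whose sequence carried several entries were left out of entry counts. Of the entries, 639 had a description in the files, which is an old match to a protein of another organism, and 287 of these said more than hypothetical, unknown or a clone name. RefSeq names of assembly AplCal3.0 matched 2 entries by accession. No genome was used, so no coordinates are given.

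Named entries were chosen by a rule fixed before the data were examined. It took the 8 largest rises and 8 largest falls with an informative description, past the threshold and of the same sign on all 8 arrays. From each of 30 gene lists it added up to 3 called members. Whatever their result, it took up to 12 memory-linked members, up to 3 sensory neuron members and up to 2 members of each cell type list. Because most probes have no gene name, 2 unnamed entries that rose and 2 that fell were also printed. Entries named only through their identifier or RefSeq lay outside the rule and were chosen after the files were seen. List tests needed at least 5 tested members, which none of the 30 lists had, so lists have counts and no test of their shift.

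The procedure was tested on simulated data made from these arrays, with 37427 probes tested and 200 of them changed. At a simulated log2 size of 0.25 it recovered 71.6% of the changed probes, at 0.5 and at 1 it recovered all 67 and all 66. It called 7 unchanged probes beside the 200. The simulated noise was independent between probes, with no effect shared through a tier or a pool of animals. The smallest simulated size lay above the median of 0.211 among the probes called in the real data. The simulation therefore checks the procedure and does not give the rate of false calls in the real data. Alternatives covered background correction, normalization, the filter on dim probes, the dye term, array weights, the eBayes prior, the probe per entry, the direction of the ratio, the authors' values, each dye orientation alone and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.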

Results

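Long-term sensitization is a lasting increase of defensive reflexes in the sea slug Aplysia after repeated noxious shock, and the pleural ganglia hold sensory neurons of these reflexes. The data compare the pleural ganglion of the shocked side with that of the unshocked side of the same animals 24 h after training, on 8 arrays of 2 animals each. Trained tissue was labelled with Cy5 on 4 arrays and with Cy3 on 4. Median spot intensity over the 8 arrays was 74.9 to 81.5 in Cy3, over a local background of 22 to 24, and 143 to 176 in Cy5, over a background of 39 to 45. Between 67.1% and 70.1% of non-control spots per array were well above background in both channels. The number of arrays sets the precision of every value below.

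The first question was which transcripts differ between the trained and the untrained side. Of 20757 tested sequence entries, 2681 were higher and 2494 were lower on the trained side at an adjusted p of 0.05 (limma, Benjamini-Hochberg, n = 8). Most differences were small, with a median of 1.17-fold among entries that rose and 1.15-fold among those that fell. Entries past 1.5-fold were mostly rises, with 215 higher and 30 lower, and past 2-fold there were 48 higher and 4 lower. The 1.5-fold split became 239 against 54 without replicate 7, 427 against 194 with the scanner software's processed signals and 285 against 166 on the arrays with trained tissue in Cy3 alone. The highest rises reached 5.24-fold and the deepest fall 3.16-fold.

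The entry with the highest fitted ratio was EB235892.1, an unnamed transcript represented by the 60-mer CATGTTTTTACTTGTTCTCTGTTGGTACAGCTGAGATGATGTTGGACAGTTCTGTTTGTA. Its log2 ratio was 2.39 ± 0.63 (SD, n = 8; limma adjusted p = 1.88e-06), and its second probe gave 2.42. EB250403.1, also unnamed, followed with a log2 ratio of 2.25 ± 0.38 (SD, n = 8; limma adjusted p = 4.46e-07), from the 60-mer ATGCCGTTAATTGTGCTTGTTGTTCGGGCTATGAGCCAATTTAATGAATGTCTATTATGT. Both were higher on the trained side on all 8 arrays, between 1.78 and 3.53 for the first and between 1.89 and 3.07 for the second. The deepest fall belonged to the unnamed entry GR212349.1, at a log2 ratio of -1.66 ± 0.36 (SD, n = 8; limma adjusted p = 1.24e-06), from the 60-mer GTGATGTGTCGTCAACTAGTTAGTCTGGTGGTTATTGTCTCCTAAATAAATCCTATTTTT. EB305050.1 had a log2 ratio of -1.09 ± 0.21 (SD, n = 8; limma adjusted p = 2e-06), from the 60-mer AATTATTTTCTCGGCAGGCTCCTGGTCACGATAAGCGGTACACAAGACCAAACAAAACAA. Both were lower on the trained side on all 8 arrays, and their second probes gave -1.59 and -0.93.

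**Figure D1:**
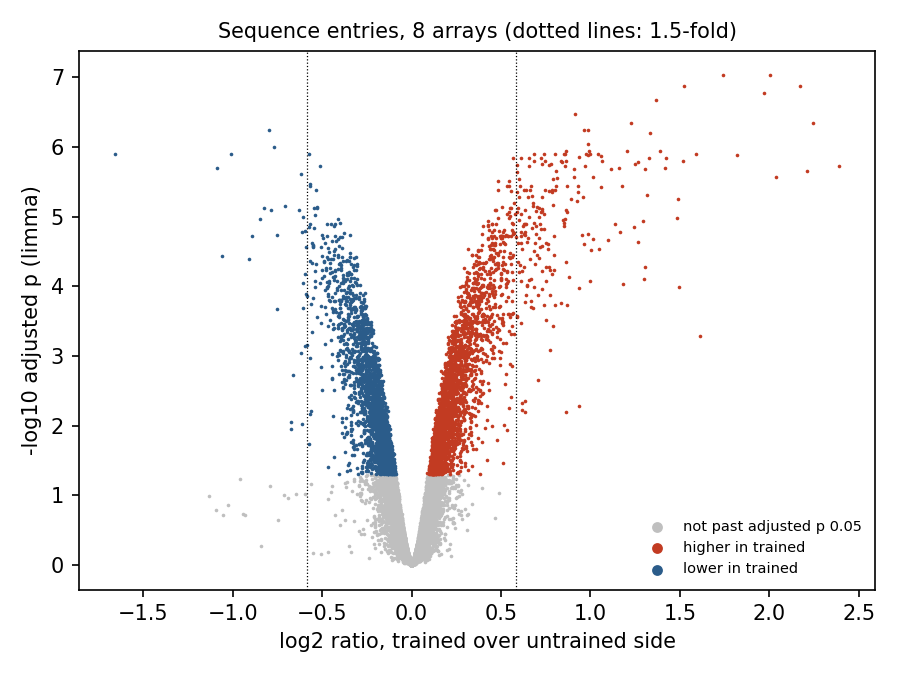
Each point is 1 of the 20757 tested sequence entries, with the log2 ratio of trained over untrained side on the x axis and the negative log10 of the limma adjusted p on the y axis; coloured points are past an adjusted p of 0.05 and dotted lines mark 1.5-fold. Beyond the dotted lines, 215 called entries lie on the right and 30 on the left.

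Among 156 tested entries whose description says more than hypothetical, unknown or a clone or gene model number, 16 rose and 12 fell. Of these 28, 5 rises and 8 falls had the same sign on all 8 arrays. At the normexp offset of 50, the largest of these 5 rises was that of 7.UF_CU.5847.C1, described as SMC4 of Trypanosoma, a family of condensin subunits that compact chromosomes, with a log2 ratio of 0.36 ± 0.20 (SD, n = 8; limma adjusted p = 0.000293). The entry of probe UF_Ac_158952_s1, described as a large protein with many transmembrane domains, rose by 0.24 ± 0.09 on the log2 scale (limma adjusted p = 0.00102). The entry 7.UF_CU.244.C2, described as golgin A2, a tether of the cis-Golgi, rose by 0.17 ± 0.08 (limma adjusted p = 0.00631). Other rises were those of a UvrD-type helicase entry, 7.UF_CU.1998.C1_MINUS, at 0.14 ± 0.10, and of a putative membrane protein, 7.UF_CU.12882.C1, at 0.11 ± 0.08. The order depended on background treatment: with processed signals the golgin A2, UvrD-type, UF_Ac_158952_s1 and SMC4-like entries had log2 ratios of 0.71, 0.51, 0.46 and 0.41.

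The largest of the 8 falls at this offset was that of the entry of probe UF_Ac_159417_s1, described as the A kinase anchor protein AKA-1, a family that holds protein kinase A near its targets, with a log2 ratio of -0.33 ± 0.14 (SD, n = 8; limma adjusted p = 0.000164). An integral membrane protein entry, 7.UF_CU.5770.C1_MINUS, followed at -0.25 ± 0.14, and an entry described as BUL1, which binds a ubiquitin ligase in yeast, 7.UF_CU.3.C3118, at -0.23 ± 0.13. Falls between -0.18 and -0.16 were measured for entries described as a Holliday junction helicase (7.UF_CU.2790.C1, -0.18 ± 0.11), doublesex (7.UF_CU.9942.C1, -0.17 ± 0.16), a sodium/hydrogen exchanger (7.UF_CU.11349.C1, -0.16 ± 0.13) and midasin (7.UF_CU.1219.C1_MINUS, -0.16 ± 0.14), a ribosome assembly factor. The smallest was of 7.UF_CU.1593.C1, described as the viral regulator ICP4, at -0.09 ± 0.03. With processed signals the midasin-like entry, at -0.56, was lower than the anchor protein entry, at -0.41, and the exchanger entry was at -0.27. The doublesex-like entry differed between dye orientations, with a mean of -0.03 on the arrays with trained tissue in Cy5 and -0.30 on those with it in Cy3 (limma adjusted p of the dye coefficient = 0.0312). These descriptions are the files' own matches to other organisms, and none of the 13 entries was measured by a second probe. The golgin A2, UvrD-like and midasin-like probes were dim, with a mean log2 brightness of 6.37, 6.36 and 6.4. They were not tested when both channels had to be well above background on all 8 arrays. The calls of the ICP4-like, membrane protein, midasin-like and UvrD-like entries, whose adjusted p was 0.0484, 0.0438, 0.0322 and 0.0176, were lost when single arrays were left out. The ICP4-like and membrane protein calls were also lost with processed signals, without background correction, with an offset of 0, with median centring, without the dye term and with the authors' values, and the UvrD-like call with median centring (limma adjusted p = 0.0751). The membrane protein call was lost with trend and robust eBayes as well (limma adjusted p = 0.0602), and the doublesex-like call without the dye term (limma adjusted p = 0.059). On the 4 arrays of 1 dye orientation alone, fewer calls held. The golgin A2, ICP4-like, membrane protein and midasin-like calls were lost in both orientations. The exchanger (-0.089, limma adjusted p = 0.328), Holliday junction helicase (0.105) and doublesex-like (0.61) calls were lost with trained tissue in Cy5, and the UF_Ac_158952_s1 (0.0546), UvrD-like (0.25) and integral membrane protein (0.144) calls with it in Cy3. The SMC4-like call held in both, at a log2 ratio of 0.21 in Cy5 (limma adjusted p = 0.0149) and 0.50 in Cy3 (limma adjusted p = 0.00571). The BUL1 and AKA-1 calls held in both as well.

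**Figure D2:**
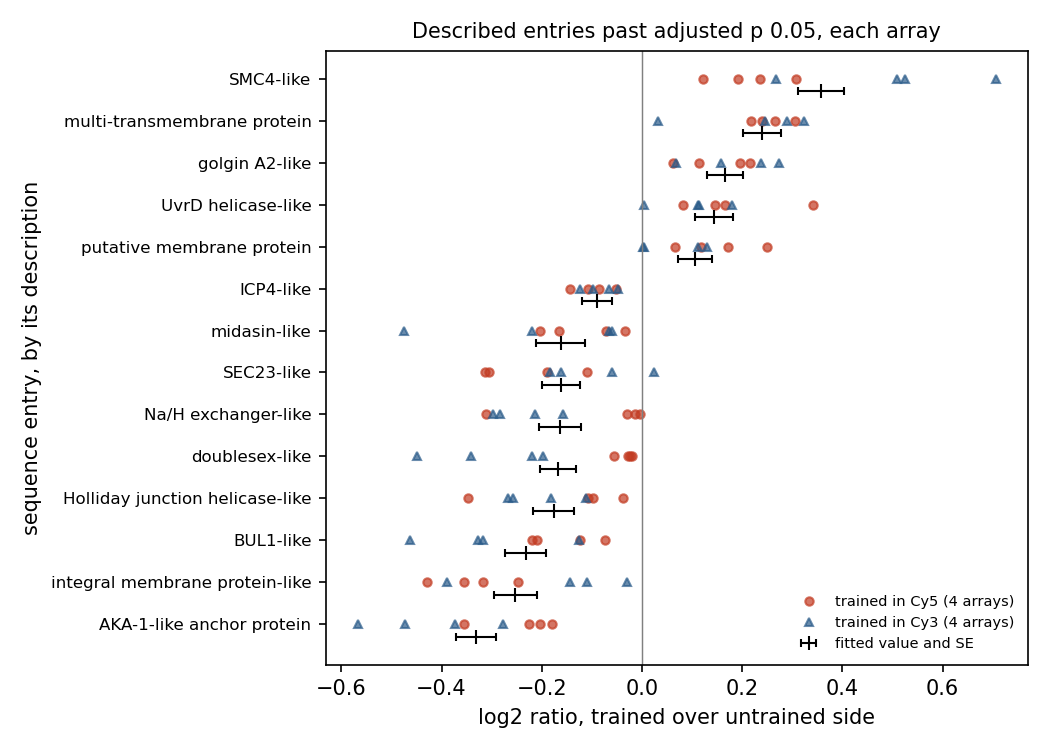
Log2 ratios of trained over untrained side (x axis) for the described entries past an adjusted p of 0.05 that the text names (y axis); circles are the 4 arrays with trained tissue in Cy5, triangles the 4 with it in Cy3, and the black marks are the fitted value ± SE. Fitted values run from 0.36 for the SMC4-like entry to -0.33 for the anchor protein entry, and the SEC23-like entry is higher on the trained side on 1 array.

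Of 30 gene lists for this tissue and treatment, 8 had a tested member and none had more than 2, since few probes carry a description. The list of endoplasmic reticulum translocation and early secretory transport had 2 tested members. Its SEC23-like entry (probe UF_Ac_159058_s1), a coat protein of vesicles leaving the endoplasmic reticulum, fell by 0.16 on the log2 scale (SD 0.12, n = 8; limma adjusted p = 0.0102) and was lower on 7 of 8 arrays; with the authors' values it had -0.14 and did not pass (limma adjusted p = 0.0734). Its log2 ratio was -0.35 with processed signals and -0.30 with an offset of 0, and on the arrays with trained tissue in Cy3 alone it was -0.095 and did not pass (limma adjusted p = 0.316). Its signal peptidase entry, 7.UF_CU.9359.C1_MINUS, had a log2 ratio of 0.10 and an adjusted p of 0.0671 by limma; adjusted over the list alone, 2 of 2 passed, in opposite directions. The cytoskeleton list had the midasin-like entry, matched through a dynein word in its description, and a profilin entry (7.UF_CU.15094.C1) at a log2 ratio of -0.02; adjusted over the list alone, 1 of 2 passed.

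The memory-linked list, which was written with knowledge of the published account of these arrays and is not independent evidence of a direction, had 1 tested member. This entry (probe UF_Ac_159243_s1) is described as the cAMP responsive element binding protein of the snail Lymnaea, a transcription factor of long-term memory. Its log2 ratio was 0.02 ± 0.12 (SD, n = 8, limma adjusted p = 0.764). The probe was dim, with a mean log2 brightness of 6.37, in the dimmest of 5 equal bins (5.98 to 6.67). It was not tested when both channels had to be well above background on all 8 arrays. With processed signals its log2 ratio was 0.15 (limma adjusted p = 0.502). These values do not show that the transcript was unchanged. The heat shock list had an Hsp70 entry (7.UF_CU.3.C867_MINUS) at 0.01, the oxidative phosphorylation list an ATP synthase subunit entry (probe UF_Ac_155659_s1) at 0.01, and the glycolysis list an aldolase entry (probe UF_Ac_158944_s1) at -0.08. The neuropeptide list had neuropeptide_precursorAY033821.1 at 0.01 ± 0.13. Of 6 cell type lists, that of hemocytes and hemolymph alone had a tested member, a hemagglutinin-related entry (7.UF_CU.9561.C1) matched through a word in its description, a bacterial protein, at -0.04 ± 0.11; this is not a measure of hemocytes. None of these 6 members passed the threshold, over all entries (limma adjusted p of 0.318 to 0.911) or adjusted over the list alone. The remaining 22 lists, those of sensory neurons and glia among them, had no tested member that the search found. It used words in identifiers, RefSeq names and descriptions, which most entries lack. An empty list therefore does not show that its transcripts were unmeasured.

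Outside the rule, 5 entries were taken because a gene name could be read in their identifier or matched through RefSeq, the neuropeptide precursor above among them. Other entries with only a sequence identifier were not looked up by gene, and known genes may be among them. These 5 therefore do not stand for the known genes on the array. The entry apnalcn had a log2 ratio of 0.00 ± 0.09, dar1 one of -0.04 ± 0.11, LOC100861465 one of 0.07 ± 0.15, and the entry whose identifier holds the word ACN4PKA one of 0.11 ± 0.22 (SD, n = 8). None of these 4 passed the threshold, with limma adjusted p of 0.975, 0.515, 0.382 and 0.263. The second probe of LOC100861465 gave 0.17 and passed, and the mean of both probes, 0.12, passed at an adjusted p of 0.0135.

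At the level of probes, 4952 of 37427 rose and 4617 fell at an adjusted p of 0.05 in limma, and 5680 passed 0.01. Of 16618 entries with 2 tested probes, both were called for 3550, with opposite signs for 4, and the log2 ratios of both probes correlated across entries at r = 0.942 (entries are not independent replicates). Where the probes shared no end-to-end stretch of 20 bases or more, r was 0.915 over 5936 entries. Past 1.5-fold, 392 probes rose and 53 fell; this split became 827 against 380 with the scanner software's processed signals, 632 against 205 with a normexp offset of 0, 517 against 272 on the arrays with trained tissue in Cy3 alone, 429 against 99 without replicate 7 and 406 against 82 without replicate 6. If trained tissue were in Cy5 on all 8 arrays, as a sentence of the label protocol reads, 1922 probes would pass, 1267 of them higher, and EB235892.1 would have a log2 ratio of -0.39 (limma adjusted p = 0.832).

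The second question was how strongly the dyes themselves shifted the ratios. The dye coefficient passed an adjusted p of 0.05 for 5405 probes (limma, n = 8), 3232 of them brighter in Cy5, and 1763 of these probes also passed for training. Its median size over all tested probes was 0.06 on the log2 scale, beside 0.07 for the training coefficient. Before any turning of sign, the Cy5 over Cy3 ratios correlated across probes at 0.45 to 0.71 between arrays of the same orientation and at -0.34 to -0.16 between arrays of opposite orientation. The dye count became 28743 with median centring in place of loess, which leaves brightness-dependent dye trends in the ratios, and 2899 with processed signals. Without replicate 1 it was 3123 and without replicate 3 it was 3180.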

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

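The tests of other splits and of the dye orientations below were chosen after the results were seen.

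Of 62 groups of 4 arrays examined, 4 held an array far from the others, where chance gives about 3.1. The sodium/hydrogen exchanger entry had a log2 ratio of -0.31 on replicate 1, against -0.03 to 0.00 on the other arrays with trained tissue in Cy5. The entry neuropeptide_precursorAY033821.1 had 0.26 on replicate 5, against 0.00 to 0.04 on the others with trained tissue in Cy3. EB305050.1 stood at -0.73 on replicate 7, against -1.30 to -1.22. The SD of log2 ratios over tested probes was 0.197 on replicate 7, against 0.303 to 0.307 on the other 3 arrays of its orientation. The doublesex-like entry differed between orientations, with a limma adjusted p of the dye coefficient of 0.0312.

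The array also carries 10 spike-in control probes, added with the labelling, which no comparison above uses. All 10 were well above background on the 8 arrays, and their mean log2 Cy5 over Cy3 ran from -2.61 to 2.99, nearly equal in both dye orientations (r = 1 across the 10). Their training coefficients had a median size of 0.011 and a largest of 0.053 on the log2 scale, with 0 of 10 at an unadjusted limma p under 0.05. The median size was 0.07 over all tested probes and 0.211 among called probes, which were selected for their size. Each spike-in value is a median over 35 spots, which by itself lowers its noise below that of a tested probe.

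The pattern weighed first is the large number of small differences between sides. Of 35 splits of the 8 arrays into 2 groups of 4, 1, the real one, gave as many probes (9569) or entries (5175) in limma. That is the smallest share 35 splits can give, so chance is argued against no further than 1 in 35. The highest of the 34 others was 0 for both, with at most 3458 probes at an unadjusted limma p under 0.05 against 13605. The slide's tiers divide the arrays exactly as the real split does, so the splits cannot tell training from tier. Of probes called on the arrays with trained tissue in Cy5 alone, 64% kept their sign on the swapped arrays, whereas a bias of the dyes alone would turn the sign. Of 3323 probes called in both orientations, 2575 (77.5%) had the same sign and the rest had opposite signs. The means of the 2 orientations correlated across probes at r = 0.37. A bias of the dyes may thus still shape part of the calls of 1 orientation. A bias between the slide's tiers that differs between probes remains open, since tier and dye orientation coincide and it would enter the training coefficient; the 10 spike-in probes had small coefficients, but they are few and not among the called probes. A response to shock on the treated side, including wounding, remains as a hypothesis, and the design has no arm that separates it from memory.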

How the results depend on the processing

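The alternatives at 2-fold, at 1.5-fold for entries, by probe name, with both probes called and without replicates 5 and 8 together were added after seeing the data. Probe counts stayed within 1.5 times of 9569 under 16 alternatives (6678 to 11319) and entry counts within that of 5175 under 17 (3546 to 5623). Quantile normalization of average brightness between arrays is counted in both. It leaves ratios as they are, so its counts of 9569 and 5175 were fixed in advance. Leaving out each array in turn gave 7565 to 9659 probes, 4103 to 5249 entries and 3123 to 5442 probes for the dye effect. Without replicates 5 and 8 together, 6682 probes passed, and 6144 of these had also passed with all 8 arrays, with the same sign. Stricter thresholds gave 5680 probes (adjusted p 0.01), 445 (1.5-fold) and 90 (2-fold), and 245 entries (1.5-fold), by construction. The dye count became 2899 with processed signals (the cause was not tested) and 28743 with median centring, which keeps brightness trends.

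With trained tissue taken as Cy5 on all arrays, the fit measures the dye effect: 1922 probes and 1314 entries passed, and 17 of 25 named entries changed sign. The 12 of these that had passed were EB235892.1 (-0.39), EB250403.1 (-0.19), SMC4-like (-0.14), golgin A2 (-0.019), midasin-like (0.044), the sodium/hydrogen exchanger (0.074), doublesex-like (0.14), the Holliday junction helicase (0.028), BUL1 (0.076), AKA-1 (0.091), EB305050.1 (0.046) and GR212349.1 (0.21). Over all 24 alternatives, 525 of 595 values of named entries kept their direction and side of the threshold or stayed short of it, and 57 fell short of it. Of the 525, 25 come from quantile normalization of average brightness, which cannot change a ratio. The changed filters on dim probes, the fit without the dye term and trend and robust eBayes also left the ratios of tested named entries as they were. Under these, only the adjusted p could change. The same holds for the mean of an entry's probes where the entry had 1 tested probe. With both channels well above background on all 8 arrays, 20 of the 25 named entries were tested. The golgin A2, UvrD-like and midasin-like entries were among those left out. The ICP4-like call was lost without any 1 of the 8 arrays (adjusted p 0.0638 to 0.119), the membrane protein call without replicate 1, 2, 3, 5, 7 or 8 (0.0533 to 0.124), midasin-like without 1, 2, 3 or 5 (0.0527 to 0.0901) and UvrD-like without 4 or 5 (0.0509 to 0.0513). No list had enough members for a test, so its alternatives gave no value. Over 5 equal bins of brightness, 7.8% of probes were called in the dimmest and 37.3% in the brightest.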

Other observations

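The tests of brightness and the offset, of repeated probes and entries, of the array surface and of the dye below were chosen after the results were seen; those of normalization and of amidation sites were not.

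Because few probes are named, 21 short protein motifs were looked for in the sense translations of the tested 60-mers, and 5 were found. All 3 sense frames were searched, with or without a stop. A short match may therefore lie outside the coding frame or arise by chance, and does not by itself identify the transcript. A run of Phe-Met-Arg-Phe-Gly followed by a basic residue, the repeat from which FMRFamide peptides are released, was present in 3 probes of 2 entries, among the brightest on the array; this motif was seen in the data before it was searched for. All 3 passed for a rise, with log2 ratios of 0.44 to 0.50 (limma adjusted p = 5.44e-05 to 0.000272, n = 8). Their values were 0.70 to 1.12 on the arrays with trained tissue in Cy5 and -0.22 to 0.38 on those with it in Cy3, and the dye coefficient passed as well (limma adjusted p at most 0.00196). A match to the EEVD tail of cytosolic heat shock proteins was found in 1 probe, which rose by 0.10 (limma adjusted p = 0.0406). A match to the linker of C2H2 zinc fingers was found in 1 probe, which fell by 0.20 (limma adjusted p = 0.00231). Myomodulin-type repeats, in 2 probes, and the RNP1 motif of RNA-binding proteins, in 2, did not pass, with the smallest adjusted p at 0.137 and 0.0633. The 2 myomodulin probes had log2 ratios of -1.03 and 0.005; the first stood at -4.13 and -3.24 on replicates 5 and 8 and at -0.87 to 0.77 on the others, and belongs to the set weighed last.

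The pattern of a dibasic amidation site, in which glycine precedes 2 basic residues as in many neuropeptide precursors, lay in an open sense frame of 671 tested probes. Of these, 92 rose and 75 fell, so 24.9% were called, beside 25.1% of other probes with an open frame. So short a pattern can also arise by chance, and the open frame need not be the coding one. The 671 probes are therefore not known to be of peptide precursors, and the similar shares do not show how such precursors responded.

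The excess of large rises over large falls was weighed next, at 88.1% of 445 probes past 1.5-fold. Compression of bright or dim spots as the whole cause is argued against by equal bins of brightness, with at least 81.4% rises in each bin with 20 or more such probes; for dim probes it stays open, since with an offset of 0 the share was 63.5% in the dimmest bin and 87.1% in the brightest. Counting each entry once left 87.8%, so repeated probes of the same entry do not account for it; whether several entries stand for the same transcript stays open, since joining those whose 60-mers shared 20 bases, which left 87.7%, joined only 2 of 245. Normalization cannot be told apart from a true excess for part of its size: the lowest share under another background correction or normalization was 68.5%, short of the bound set beforehand for excluding it, though rises still outnumbered falls. A stronger induction than repression of transcripts 24 h after training is a candidate explanation that was not tested separately.

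A set of 18 probes from 10 entries was far lower on the trained side of replicates 5 and 8, with medians of -3.27 and -3.26 on the log2 scale, and, by the way it was chosen, within 1 log2 unit of 0 on the other 6 arrays. None of the other 27 pairs of arrays had such a set in either direction, and in limma 0 of the 18 probes passed for training (10 at an unadjusted p under 0.05). A local defect of the array is argued against by the second probes, which were below -1 on both replicates for 100% of 8 entries. The test of a dye effect took the 26 probes at -2 or lower on replicates 5 and 8, whatever their other arrays. On replicates 6 and 7, labelled the same way, their median was 0.076 (from -2.27 to 2.92). The 26 include all 18 probes of the set, which lie within 1 log2 unit of 0 there by choice. The median could therefore not reach the -1 that a dye effect called for, so a dye effect stays undecided. Peptide-secreting cells carried over with the untrained side's ganglion may contribute. Of the 18 probes, 13 had an open frame, and 1 of these held the amidation site pattern, against 670 of 29722 others (Fisher's exact test, one-sided p = 0.257). These are too few to decide, and the open frame need not be the coding one. A difference between the pooled animals' 2 sides remains open and was not tested.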
